A study of Homo sapiens with 42 samples.

How the data were processed

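The deposited value table held 40641 probe sets on 42 arrays as log2 values, which the authors' labels describe as RMA-normalized. Per the submitters' processing notes RMA was run with the oligo package, whose version is not given in the sources used here. The deposited values were rounded to 0.1 log2 and ran from 0.3 to 13.7, with array medians over genes of 6.1 to 6.2. They were used as deposited, without further normalization, background correction or removal of arrays. Raw intensity files were not used here. Each column was assigned to its sample through the sample titles, with 0 columns left over.

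Of the probe sets, 18566 had one gene symbol, 1244 several and 20831 none listed. Only those with one symbol entered the tests. Current symbols were assigned to 17150 of them through Entrez identifiers, and 1416 kept the symbol of the platform. Where a gene had several probe sets (329 genes) the one with the highest mean over all arrays was kept, which left 17553 genes.

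Differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a single fit of 11 group means over time label and siRNA. The residual degrees of freedom were 31, the prior degrees of freedom 4.07, the prior SD 0.0797 and the median residual SD 0.0871 log2. With so small a spread many genes with small differences pass, so changes of at least 1 log2 unit were counted separately. The fit served 19 comparisons: 3 between time labels in controls, 8 of a knockdown with controls of its time label, 3 between knockdowns at 144 h and 5 between the effects of a knockdown at 2 time labels. Within each comparison p-values were adjusted by Benjamini and Hochberg over the 17553 genes, and a gene passed with an adjusted p under 0.05. Errors are SE of the log2 difference unless SD is stated. The numbered siRNA sets of a target were averaged as arrays of one group, and replicate number was not modelled. These choices, the alternatives and the gene lists were fixed before the data were examined, apart from those named in the sensitivity paragraph as added later.

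Genes were named by rule. For each 144 h knockdown against controls and for 144 h against 0 h controls these were the 8 largest rises and the 8 largest falls among genes that passed and had every array of one group above every array of the other. For the other comparisons these were the 4 largest of each. JUN, RELA, ETS1, HRAS and up to 4 members of each list with the largest absolute change were added, and uncharacterized, non-coding and sex-linked genes were left out.

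The 31 gene lists were written from general knowledge of fibroblast senescence and of the pathways concerned. Each was tested with camera in limma with a correlation between genes of 0.01, and again with an estimated correlation, over 589 list by comparison tests adjusted together. Of these 164 passed, 3 passed with the estimated correlation and 136 passed when the 30% of genes with the lowest mean were left out. Members past the threshold were counted with p-values adjusted over all genes and over the list alone, and a list-alone count is printed where it differs. The directions of the lists were checked after a second quantile normalization and after subtraction of each array's median. Of the lists that passed only oxidative phosphorylation with siJUN at 72 h changed direction, from 4 genes lower to 2 higher and 1 lower after median subtraction.

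The programme score used the 0 h controls and the 4 odd-numbered 144 h controls to define risen and fallen genes with at least 1 log2 unit. Knockdown arrays were compared only with the even-numbered 144 h controls, by an exact permutation test of the mean. Correlations between changes that share controls were set beside those with split controls and beside 100 simulations of unchanged groups with the residual spread of each gene.

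The limma fit, but not the list, score or overlap steps, was tested on simulated arrays. These had 200 changed genes among 17553 and the group sizes of 3 comparisons. Changes of 0.5 log2 were recovered for 78%, 91% and 97% of genes with the sizes of siJUN at 72 h, siRELA at 0 h and siJUN at 144 h, and changes of 1 log2 for 99%, 100% and 100%. Of the calls 7.81%, 4.5% and 2.96% were false. The simulated arrays were independent, whereas real arrays of one siRNA set correlated at 0.24. The false rates therefore do not carry over to the counts in the results. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.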

Results

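Gene expression was measured on 42 Affymetrix arrays from WI38 cells, which are human lung fibroblasts. The cells carried a RAS oncogene fused to the oestrogen receptor, which 4-hydroxytamoxifen (4OHT, 400 nM) switches on. Sustained RAS signalling drives such cells into oncogene-induced senescence, a lasting growth arrest with secretion of inflammatory factors. Small interfering RNAs (siRNAs) against JUN, RELA or ETS1, which encode an AP-1 subunit, an NF-kB subunit and an ETS factor, or non-targeting controls were, per the submitters' design, transfected ahead of 4OHT or after 72 or 144 h of it. The 0 h arrays comprised 4 controls, 2 with siJUN, 4 with siRELA and 4 with siETS1. The 72 h arrays comprised 2 controls, 2 with siJUN and 4 with siRELA. The 144 h arrays comprised 8 controls and 4 with each of the 3 siRNAs. Arrays with a targeting siRNA carried a set number, 1 or 2, whose meaning the labels do not give, and siJUN at 0 and 72 h came from set 1 alone. The labels list 400 nM 4OHT for all 42 arrays, those at 0 h included. They do not state the time between transfection and collection, nor when cells labelled 0 h met 4OHT. The exposure behind each contrast, with a knockdown or between time labels, is therefore open. The labels are not known to be collection times. The number of arrays limits the precision, and each p-value measures only the spread between arrays, which can be technical, since nothing states that replicates were separate cultures.

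The first question was whether each siRNA lowered its own target. JUN is an AP-1 subunit that pairs with FOS proteins at stress and growth genes. RELA is the main activating subunit of NF-kB, which drives inflammatory genes, and ETS1 is a transcription factor activated downstream of RAS and ERK. With siJUN, JUN fell at 0 h (log2 change -0.30 ± 0.07 SE, adjusted p = 0.00124), at 72 h (-0.70 ± 0.08, adjusted p = 4.66e-08) and at 144 h (-0.31 ± 0.05, adjusted p = 5.57e-07). Its mean level moved from 8.15 ± 0.06 (SD, n = 4) to 7.85 ± 0.07 (n = 2) at 0 h and from 7.54 ± 0.05 (n = 8) to 7.22 ± 0.05 (n = 4) at 144 h. The 0 h fall did not pass without 0 h siJUN replicate 2, where it was -0.25 (adjusted p = 0.056), and the 72 h fall did not pass with only the compared groups in the fit (-0.70, adjusted p = 0.061). RELA fell with siRELA at 0 h (-1.67 ± 0.06, adjusted p = 8.04e-21), 72 h (-1.53 ± 0.08, adjusted p = 1.42e-16) and 144 h (-0.86 ± 0.05, adjusted p = 5.82e-15), and ETS1 fell with siETS1 at 0 h (-1.03 ± 0.07, adjusted p = 2.28e-13) and 144 h (-1.51 ± 0.06, adjusted p = 1.53e-20). In controls JUN fell between 0 and 144 h (-0.61 ± 0.05, adjusted p = 3.68e-14), RELA rose (0.39), ETS1 fell (-0.44) and HRAS did not pass (-0.01). The untargeted factors also moved in some groups. ETS1 rose with siJUN at 0 h (0.25) and 144 h (0.44), RELA fell with siJUN at 144 h (-0.24), and JUN fell with siRELA at 72 h (-0.42). With siETS1 at 0 h JUN rose (0.20) and RELA fell (-0.20).

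**Figure D1:**
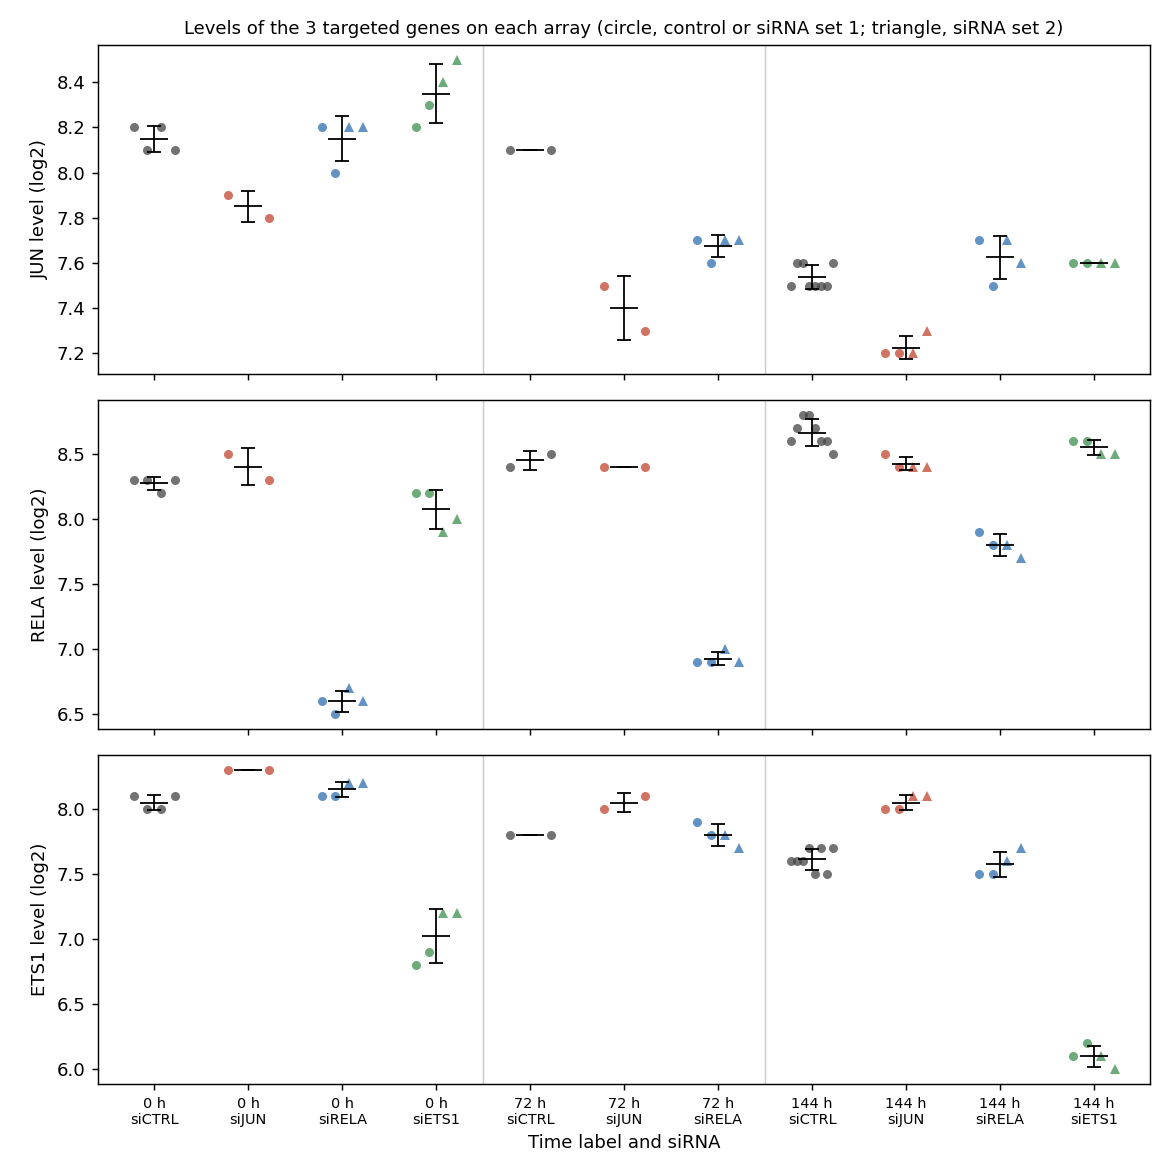
Log2 level of JUN, RELA and ETS1 (vertical axes) on each array by time label and siRNA (horizontal axis), with black bars for the mean and SD of each group. JUN levels with siJUN lay below those of the controls of the same time label, from 7.85 against 8.15 at 0 h to 7.22 against 7.54 at 144 h.

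The comparison of 144 h with 0 h controls asked which genes differed between these time labels. Senescent fibroblasts are known for a growth arrest and for secreted cytokines and chemokines. SERPINB4, a serine protease inhibitor, PTGS2, which makes prostaglandins, and EGR1, an immediate early factor of ERK signalling, rose furthest. LRRN3, a leucine-rich repeat protein of neurons, the carboxypeptidase CPA4 and the semaphorin SEMA6A fell furthest. Of 17553 genes, 635 rose and 665 fell by at least 1 log2 unit, and 13348 passed at any size (6511 higher, 6837 lower). The 8 largest rises were SERPINB4 (4.76 ± 0.26), PTGS2 (4.57 ± 0.21), EGR1 (4.42 ± 0.19), POMK (4.14 ± 0.21), PI3 (3.92 ± 0.15), NR4A2 (3.64 ± 0.18), TFPI2 (3.52 ± 0.11) and IL24 (3.50 ± 0.17). The 8 largest falls were LRRN3 (-5.08 ± 0.19), CPA4 (-5.02 ± 0.13), SEMA6A (-4.98 ± 0.18), LCE2A (-4.59 ± 0.22), SCN9A (-4.09 ± 0.18), LPPR4 (-4.01 ± 0.17), FAM180A (-3.79 ± 0.16) and CNN1 (-3.78 ± 0.16). No array came from cells kept for 144 h without 4OHT, so time in culture was not separated from RAS.

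Secreted factors and matrix genes moved in several directions between 0 and 144 h. Cytokines and chemokines of the secretory phenotype recruit and activate immune cells. Of 20 measured, 16 rose and 2 fell, among them CCL20 (3.19) and IL11 (2.66) upward and IL1B (-2.83) downward (adjusted p = 5.3e-05, adjusted p = 0.25 with an estimated correlation). Contractile genes, which build the actin stress fibres of myofibroblasts, fell for 13 of 14, with TAGLN (-2.50), MYOCD (-2.20) and ACTG2 (-2.08) beside CNN1 (adjusted p = 2.3e-06, adjusted p = 0.093 with an estimated correlation). TGF-beta targets rose for 10 of 15 and fell for 2, with TGFB1 (2.11), SKIL (1.79) and SMAD6 (1.39) highest (adjusted p = 0.016, adjusted p = 0.23 with an estimated correlation). Matrix proteases split into 9 higher and 5 lower of 17, such as MMP3 (1.67) and MMP1 (-2.24), and did not pass as a list (adjusted p = 0.59). Fibrillar collagen and matrix genes split into 11 higher and 12 lower of 26, such as TNC (1.64) and DCN (-1.86). The counts adjusted over the list alone were the same for these lists, apart from a sixth protease that fell.

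Cell-cycle, signalling and metabolic genes formed other groups. DNA replication genes copy the genome in S phase, and mitosis genes part the copies. Replication genes rose for 21 of 26 and fell for 2, with DTL (1.34), GINS1 (1.33), CDC6 (1.24) and RRM2 (1.22) leading (adjusted p = 7.8e-05, adjusted p = 0.4 with an estimated correlation). Mitosis genes rose for 17 of 29 and fell for 4, with AURKB (0.89) up and CENPF (-0.80) down (adjusted p = 0.029, adjusted p = 0.61 with an estimated correlation). The p53 targets, which act in arrest and repair, fell for 13 of 18 and rose for 4, led by GADD45A (-2.31), ZMAT3 (-2.05) and FAS (-1.70) (adjusted p = 0.024, adjusted p = 0.56 with an estimated correlation). CDKN1A, the p53-driven inhibitor of cyclin-dependent kinases, fell (-0.59), as did CDKN1B (-0.63), while CDKN2A rose (0.34). Higher replication genes and lower CDKN1A are not the direction of a growth arrest, and cell division was not measured. Outputs of RAS and ERK rose for 16 of 24 and fell for 4, with SPRY4 (1.86) and IER3 (1.55) next to EGR1 (adjusted p = 0.02, adjusted p = 0.41 with an estimated correlation). Interferon-stimulated genes, the antiviral response, rose for 23 of 26 and fell for 2, with IFI6 (2.55), IFI44 (2.29), USP18 (2.07) and CXCL10 (1.95) (adjusted p = 1.1e-05, adjusted p = 0.45 with an estimated correlation). Among the 144 h controls replicate 6 stood apart on this list, with a mean level of 7.01 against 6.72 on the next array. The same controls serve the knockdown comparisons of this list at 144 h. Cholesterol biosynthesis genes rose for 16 of 18 and fell for 1, with INSIG1 (2.36), HMGCS1 (1.97) and SQLE (1.82) (adjusted p = 1.3e-06, adjusted p = 0.37 with an estimated correlation). The counts adjusted over the list alone were the same for these 6 lists.

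The remaining lists did not pass between 0 and 144 h. AP-1 family genes rose for 11 of 18 and fell for 6, with FOS (2.69), JUNB (2.09) and FOSB (1.82) up while JUN fell (adjusted p = 0.24). ETS family genes rose for 11 of 20 and fell for 6, such as ETV6 (1.34) and ELK3 (-0.93), and NF-kB genes rose for 11 of 21 and fell for 7, such as ICAM1 (0.89) and PTX3 (-1.61). Antigen presentation genes rose for 9 of 14 and fell for 3 (adjusted p = 0.055), and IL-1 pathway genes rose for 8 of 11 and fell for 3, with IL1R1 at 2.40. Chromatin genes known to be lost in senescence rose for 6 of 10 and fell for 2, and CDK inhibitors rose for 2 of 7 and fell for 4. Counts of higher and lower genes were 6 and 5 of 18 for the unfolded protein response, 5 and 5 of 14 for the Notch pathway, 8 and 9 of 19 for the lysosome, 9 and 11 of 23 for glycolysis and hypoxia, 5 and 8 of 18 for oxidative phosphorylation, 4 and 9 of 16 for ribosomal proteins, 5 and 6 of 11 for housekeeping genes and 5 and 2 of 7 for RNA interference. Marker lists gave 5 and 2 of 8 for leukocytes, 3 and 2 of 9 for epithelium, 1 and 5 of 8 for endothelium, 2 and 2 of 6 for neural cells and 4 and 7 of 15 for fibroblasts. LAPTM5 (2.44) and KRT18 (2.10) rose and KRT19 (-1.16), TEK (-1.80), NT5E (-1.41) and THY1 (-1.22) fell. Median, mean and test differed in sign for the matrix, unfolded protein, Notch, lysosome, glycolysis and fibroblast lists.

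The 72 h controls addressed which changes were present at the middle time label. ERK feedback genes damp RAS signalling, and IL1A and IL1B start the inflammatory cascade of senescent cells. TFPI2, an inhibitor of matrix proteases, EGR1 and MMP3, a stromelysin, were higher at the 72 h than at the 0 h label, and the contractile gene CNN1 was lower. From 0 to 72 h, 76 genes rose and 97 fell by at least 1 log2 unit, and 5004 passed at any size (2586 higher, 2418 lower, and 1927 and 2558 after each array's median was subtracted). TFPI2 (2.72 ± 0.16), EGR1 (2.32 ± 0.27), SLC6A15 (2.12 ± 0.14) and MMP3 (2.0 ± 0.20) rose most, and LRRN3 (-2.85 ± 0.27), LPPR4 (-2.42 ± 0.24), CPA4 (-2.27 ± 0.18) and GALNT5 (-2.20 ± 0.26) fell most. EREG (1.75), SPRY4 (1.57), IL1A (1.23) and ICAM1 (1.02) rose, while DCN (-2.00), CNN1 (-1.40), TAGLN (-1.18) and LMNB1 (-0.65) fell. Outputs of RAS and ERK rose for 12 of 24 and fell for 2 (14 and 2 adjusted over the list alone, adjusted p = 6.9e-06, adjusted p = 0.16 with an estimated correlation). Contractile genes fell for 10 of 14 (the same adjusted over the list alone, adjusted p = 3e-07, adjusted p = 0.074 with an estimated correlation). Replication genes rose for 4 of 26 and fell for 1 (adjusted p = 0.3), interferon-stimulated genes rose for 4 of 26 and fell for 1 (3 and 1 over the list alone, adjusted p = 0.097), and neither list passed. The 72 h comparison rested on 2 controls, and its count was 2925 without 72 h control replicate 1, 2912 without replicate 2 and 2924 with the siRNA set as a random block.

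Between 72 and 144 h, 253 genes rose and 225 fell by at least 1 log2 unit, and 9524 passed at any size (4483 higher, 5041 lower, and 4473 and 4365 after median subtraction). The elafin gene PI3 and the ferroxidase HEPHL1 joined SERPINB4 and PTGS2 among the rises between these labels, whereas IL1B, high at 72 h, fell. SERPINB4 (5.64 ± 0.33), PI3 (4.05 ± 0.20), HEPHL1 (3.61 ± 0.24) and PTGS2 (3.58 ± 0.28) rose most, and LCE2A (-4.01 ± 0.29), IL1B (-3.52 ± 0.22), SCN9A (-2.84 ± 0.23) and SEMA6A (-2.83 ± 0.23) fell most. CXCL5 (2.63), IL6 (2.56), IFI6 (2.50), INSIG1 (1.89) and TGFB1 (1.56) rose, and ETV1 (-1.10), NT5E (-1.09) and ZMAT3 (-1.50) fell. Replication genes rose for 23 of 26 and fell for 1 (2 over the list alone, adjusted p = 8.9e-07, adjusted p = 0.3 with an estimated correlation), and cholesterol genes rose for 17 of 18 and fell for 1 (adjusted p = 1.8e-10, adjusted p = 0.25 with an estimated correlation). Interferon-stimulated genes rose for 22 of 26 and fell for 1 (adjusted p = 9.4e-07, adjusted p = 0.4 with an estimated correlation).

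JUN knockdown at 144 h addressed how far AP-1 holds the 144 h expression programme in place. AP-1 dimers bind enhancers of cytokine, protease and growth genes. Here the chemokines CCL20, CXCL5 and CXCL1, the cytokine IL24 and the prostaglandin enzyme PTGS2 fell. Contractile genes such as TAGLN and CNN1 rose, as did CPA4 and SEMA6A, which had fallen from 0 to 144 h in controls. Changes of at least 1 log2 unit numbered 224 upward and 150 downward, and 10188 passed at any size (4836 higher, 5352 lower). Higher genes made up 47.5% of the calls, and 68.9% after each array's median was subtracted. The 8 largest falls were SERPINB4 (-4.74 ± 0.26), PI3 (-3.70 ± 0.15), PTGS2 (-3.65 ± 0.21), CCL20 (-3.11 ± 0.19), HEPHL1 (-3.09 ± 0.19), CXCL5 (-2.95 ± 0.11), IL24 (-2.82 ± 0.17) and NR4A2 (-2.71 ± 0.18). The 8 largest rises were LCE2A (3.29 ± 0.22), CPA4 (3.23 ± 0.13), SEMA6A (3.13 ± 0.18), LRRN3 (3.00 ± 0.19), SCN9A (2.74 ± 0.18), CAVIN4 (2.53 ± 0.19), ALPK2 (2.33 ± 0.14) and LPCAT2 (2.31 ± 0.14).

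Secretory genes fell with siJUN for 14 of 20 and rose for 3, with CXCL1 at -1.97 and IL1B at 1.18 (the same adjusted over the list alone, adjusted p = 3.3e-06, adjusted p = 0.19 with an estimated correlation). Contractile genes rose for 13 of 14 and fell for 1, led by TAGLN (1.58), CNN1 (1.58), MYOCD (1.45) and CALD1 (1.38) (the same over the list alone, adjusted p = 1.5e-08, adjusted p = 0.057 with an estimated correlation). Replication genes fell for 22 of 26 and rose for 2, with DTL (-1.11), MCM3 (-1.02) and GINS1 (-0.97) lowest (adjusted p = 3.6e-08, adjusted p = 0.26 with an estimated correlation). Mitosis genes fell for 25 of 29, and 1 rose when adjusted over the list alone, with TOP2A (-0.84) and NDC80 (-0.70) lowest (adjusted p = 1.5e-06, adjusted p = 0.3 with an estimated correlation). The p53 targets rose for 14 of 18 and fell for 2, led by GADD45A (1.61) and FAS (1.25), and CDKN1A rose (0.46) (adjusted p = 3.1e-05, adjusted p = 0.31 with an estimated correlation). Interferon-stimulated genes fell for 19 of 26 and rose for 2, such as CXCL10 (-1.50) and IFI6 (-1.30) (adjusted p = 0.00046, adjusted p = 0.55 with an estimated correlation). Within the AP-1 family 10 of 18 fell and 2 rose, with FOS (-1.54), FOSB (-1.22) and JUNB (-1.14) lowest, and the list did not pass (adjusted p = 0.053). Proteases rose for 7 of 17 and fell for 7, with MMP10 (-1.60) down and MMP1 (1.54) up. Of the markers of other cell types, leukocyte markers fell for 4 of 8 and rose for 1, with LAPTM5 at -1.81 (adjusted p = 0.43), endothelial markers rose for 4 of 8, with TEK at 1.08 (adjusted p = 0.4), and neither list passed. Their mean levels moved from 5.91 ± 0.02 (SD) to 5.61 ± 0.03 and from 5.84 ± 0.04 to 6.08 ± 0.03. EGR1 (-2.20), IL1R1 (-2.12) and TGFB1 (-0.99) fell, and TGFB2 (1.84), FBN2 (1.31) and LOX (1.19) rose.

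RELA knockdown at 144 h addressed the part of NF-kB. NF-kB controls its own inhibitors, chemokines and antigen presentation, and overlaps with the interferon response. IL24, CXCL1, the interferon-stimulated IFI6, IFI27, DTX3L and CXCL10, and the NF-kB inhibitor genes TNFAIP3 and NFKBIA fell. The interleukins IL1A and IL1B, the plasminogen activator PLAT and the integrin ITGA8 rose. RELA knockdown raised 101 genes and lowered 69 by at least 1 log2 unit, and 7754 passed at any size (3532 higher, 4222 lower). Higher genes made up 45.6% of the calls, and 73.9% after each array's median was subtracted. The count was 4715 with the siRNA set as a random block and 4727 with control replicates 1 and 2 alone. The 8 largest falls were IL24 (-2.55 ± 0.17), IFI6 (-2.50 ± 0.20), PI3 (-2.37 ± 0.15), SERPINB4 (-2.19 ± 0.26), IFI27 (-2.04 ± 0.23), CXCL1 (-1.97 ± 0.17), DTX3L (-1.81 ± 0.18) and CXCL10 (-1.77 ± 0.21). The 8 largest rises were LCE2A (3.44 ± 0.22), KRTAP1-5 (2.89 ± 0.19), SEMA6A (2.35 ± 0.18), CPA4 (2.30 ± 0.13), ITGA8 (2.09 ± 0.23), LCE1F (2.08 ± 0.17), SCN9A (2.04 ± 0.18) and CAVIN4 (2.03 ± 0.19).

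With siRELA, interferon-stimulated genes fell for 24 of 26, among them IFIH1 (-1.60) (adjusted p = 1.9e-12, adjusted p = 0.25 with an estimated correlation). Antigen presentation genes fell for 13 of 14, such as ERAP1 (-0.62) and HLA-B (-0.57) (adjusted p = 1.1e-06, adjusted p = 0.098 with an estimated correlation). NF-kB genes fell for 14 of 21 and rose for 4, with TNFAIP3 (-1.59), IRAK2 (-1.16) and NFKBIA (-1.06) lowest (adjusted p = 0.00013, adjusted p = 0.4 with an estimated correlation). Secretory genes fell for 13 of 20 and rose for 5, with IL1A (1.38) and IL1B (1.35) among the latter (adjusted p = 0.0041, adjusted p = 0.38 with an estimated correlation). Each of the 29 mitosis genes fell, with TOP2A (-1.51), CCNA2 (-1.20), MKI67 (-1.16) and KIF11 (-1.07) lowest (adjusted p = 5.4e-19, adjusted p = 0.057 with an estimated correlation). Replication genes fell for 23 of 26, such as DTL (-1.14) (adjusted p = 8.5e-11, adjusted p = 0.19 with an estimated correlation), and cholesterol genes for 17 of 18, such as HMGCS1 (-1.72) (adjusted p = 1.1e-09, adjusted p = 0.26 with an estimated correlation). Contractile genes rose for 10 of 14, with CNN1 (1.53), ACTG2 (1.35), TAGLN (1.28) and ACTA2 (1.10) (adjusted p = 2.5e-09, adjusted p = 0.057 with an estimated correlation). Matrix genes rose for 15 of 26 and fell for 5, with POSTN (1.40) and FBLN5 (1.21) highest (adjusted p = 0.00092, adjusted p = 0.43 with an estimated correlation). The proteases MMP12 (1.53), PLAT (1.38) and MMP3 (0.90) rose, as did the CDK inhibitor CDKN2B (1.33), and FOS (-0.91) and CTSS (-1.30) fell. Leukocyte markers fell for 4 of 8 and rose for 1 (adjusted p = 0.4), with LAPTM5 at -1.39, and endothelial markers rose for 5 of 8 and fell for 1 (adjusted p = 0.37), and neither list passed.

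ETS1 knockdown at 144 h asked the same of an ETS factor downstream of RAS. ETS factors bind beside AP-1 at protease and immediate early genes. FOS, the proteases MMP10 and ADAMTS5 and the antiviral genes IFI27 and OAS2 fell, and the NF-kB inhibitor TNFAIP3 and the pyrophosphatase ENPP1 rose. By at least 1 log2 unit 18 genes rose and 39 fell, and 7125 passed at any size (3999 higher, 3126 lower). The siETS1 sets differed, and the count was 3593 with the siRNA set as a random block, 4568 with the replicate number as a block and 3559 with control replicates 1 and 2 alone. The 8 largest falls were FOS (-2.01 ± 0.16), MMP10 (-1.77 ± 0.21), ADAMTS5 (-1.75 ± 0.13), SLITRK6 (-1.56 ± 0.14), IFI27 (-1.56 ± 0.23), OAS2 (-1.52 ± 0.20), ETS1 itself (-1.51 ± 0.06) and CA8 (-1.49 ± 0.15). The 8 largest rises were KRTAP1-5 (1.76 ± 0.19), ENPP1 (1.53 ± 0.17), SERPINB7 (1.47 ± 0.20), ARRDC4 (1.34 ± 0.08), TNFAIP3 (1.31 ± 0.14), CSRP2 (1.30 ± 0.15), CPA4 (1.20 ± 0.13) and TREM1 (1.15 ± 0.14). Interferon-stimulated genes fell for 22 of 26, such as IFIH1 (-1.07) and IFI44 (-0.91) (adjusted p = 9.3e-11, adjusted p = 0.29 with an estimated correlation). Antigen presentation genes fell for 9 of 14, such as HLA-C (-0.45) (adjusted p = 0.00015, adjusted p = 0.23 with an estimated correlation). Outputs of RAS and ERK fell for 13 of 24 and rose for 2, with EGR1 (-0.90), DUSP1 (-0.65) and DUSP6 (-0.61) lowest (adjusted p = 0.00085, adjusted p = 0.27 with an estimated correlation). Ribosomal protein genes rose for 11 of 16, such as RPS19 (0.40) (12 over the list alone, adjusted p = 0.00018, adjusted p = 0.31 with an estimated correlation). Secretory genes rose for 5 of 20 and fell for 4, with CCL20 (1.04) and CXCL3 (-0.70) at the ends, and did not pass (adjusted p = 0.88). CCL20 changed by 1.74 with set 1 and 0.34 with set 2, and CXCL3 did not pass with set 1 alone (-0.32, adjusted p = 0.28) or with the set as a random block (adjusted p = 0.059). Contractile genes, split into 3 higher and 2 lower of 14 (2 and 4 after a second quantile normalization), replication genes (1 and 5 of 26) and mitosis genes (2 and 6 of 29) did not pass either. FOSB (-1.22), ATF3 (-0.75), TGFB2 (-0.96) and GDF15 (-0.72) fell. Endothelial markers fell for 2 of 8 (adjusted p = 0.27) and leukocyte markers for 1 of 8, with 1 higher (adjusted p = 0.95).

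**Figure D2:**
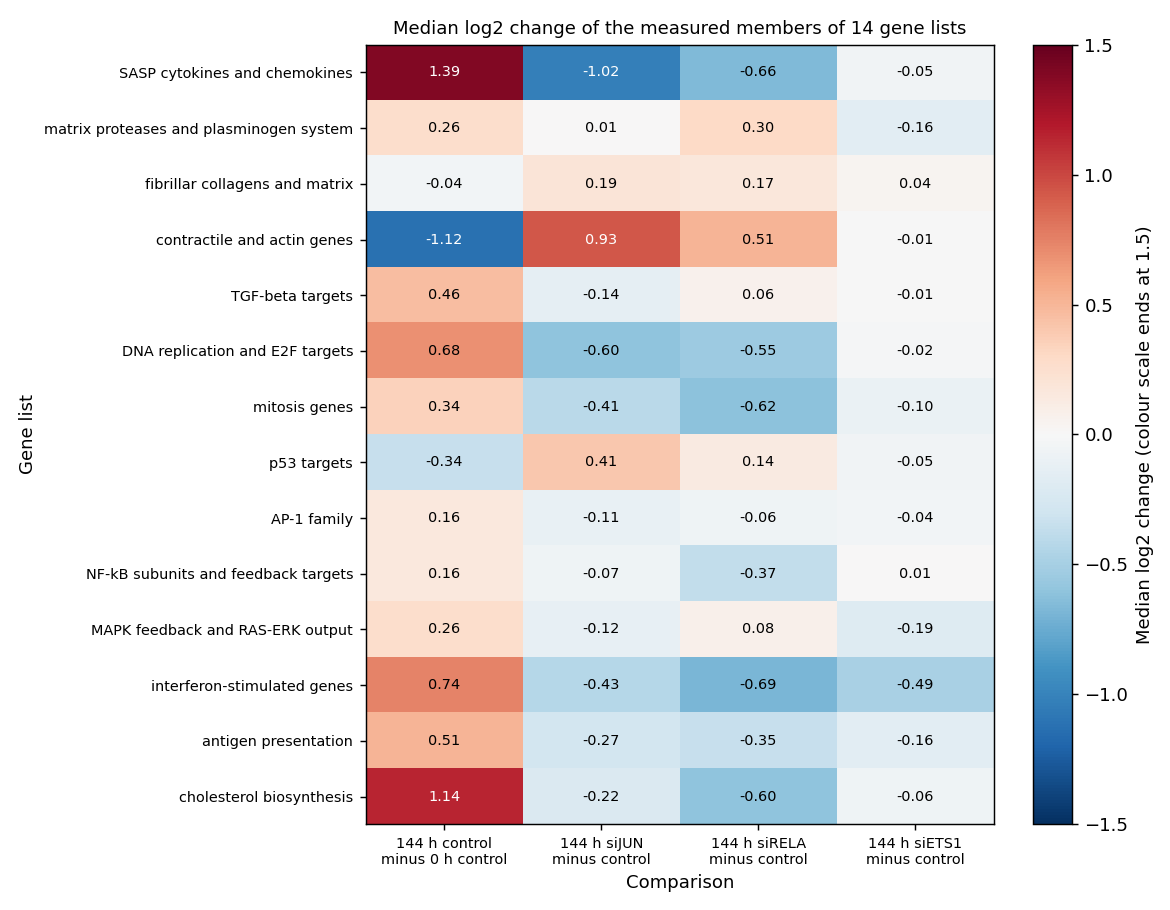
Median log2 change of the measured members of 14 gene lists (vertical axis) in 4 comparisons (horizontal axis), with colour from blue (lower) to red (higher). The contractile list stood at -1.12 from 0 to 144 h in controls and at 0.93 with siJUN at 144 h, and small medians changed sign after rescaling for NF-kB genes with siJUN, AP-1 genes with siRELA and contractile genes with siETS1.

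Direct contrasts between knockdowns at 144 h used no control array. JUN against RELA knockdown set an AP-1 subunit against an NF-kB subunit. With siJUN the matrix proteases MMP10 and MMP12 and the ERK output EGR1 were lower, and the NF-kB inhibitor TNFAIP3 and the mechanical stress gene ANKRD1 were higher. At least 1 log2 unit separated 39 genes upward and 87 downward with siJUN, of 7156 past the threshold. ANKRD1 (1.93 ± 0.17), TNFAIP3 (1.83 ± 0.16), HAS2 (1.60 ± 0.34) and DOCK9 (1.53 ± 0.09) were highest, and MMP12 (-2.65 ± 0.22), SERPINB4 (-2.55 ± 0.29), MMP10 (-2.48 ± 0.24) and PAQR5 (-2.42 ± 0.06) lowest. Secretory genes were lower with siJUN for 11 of 20 and higher for 1, with CCL20 (-1.85), LIF (-1.70) and CXCL5 (-1.65) (adjusted p = 7.2e-05, adjusted p = 0.25 with an estimated correlation). Mitosis genes were higher with siJUN for 17 of 29 and lower for 2, such as ANLN (0.88) (18 and 2 over the list alone, adjusted p = 9.3e-05, adjusted p = 0.4 with an estimated correlation), and p53 targets were higher for 10 of 18 and lower for 1, such as FAS (1.20) (11 and 2 over the list alone, adjusted p = 0.00027, adjusted p = 0.37 with an estimated correlation). Between siJUN and siETS1, 293 genes were higher and 156 lower by at least 1 log2 unit, of 10236 past the threshold, and the higher share moved from 44.3% to 61.3% after median subtraction. LCE2A (3.35 ± 0.26) and TGFB2 (2.80 ± 0.20) were highest, and PTGS2 (-4.35 ± 0.25), PI3 (-4.20 ± 0.18), CCL20 (-4.15 ± 0.22) and TREM1 (-3.85 ± 0.16) lowest. Between siRELA and siETS1, 196 were higher and 81 lower, of 9410, and the higher share moved from 44.0% to 62.4%. ITGA8 (3.40 ± 0.26) and SLITRK6 (3.38 ± 0.16) were among the highest with siRELA, and TNFAIP3 (-2.90 ± 0.16) and PI3 (-2.87 ± 0.18) lowest.

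A programme score asked how far each knockdown moved the cells back along the 0 to 144 h change. It was the mean of the genes that rose minus the mean of those that fell by at least 1 log2 unit, 646 and 699 genes defined with the odd-numbered 144 h controls, and scaled to 0 in 0 h controls and 1 in the 4 even-numbered 144 h controls (0.94 to 1.05). With siJUN the score was 0.46 ± 0.04 (SD, n = 4, 0.41 to 0.49), and with siRELA 0.72 ± 0.02 (n = 4, 0.69 to 0.75). Each had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 arrays can give (0.0429 adjusted over 3 knockdowns). With siETS1 the score was 0.91 ± 0.09 (n = 4, 0.82 to 0.99, exact permutation p = 0.143), and its sets lay apart, at 0.98 ± 0.01 (n = 2) for set 1 and 0.83 ± 0.02 (n = 2) for set 2, below the lowest held-out control of 0.94. At the earlier time labels the scores with siJUN and siRELA lay above those of controls, a difference that was not tested. At 0 h they were 0.16 ± 0.02 (n = 2) with siJUN, 0.12 ± 0.02 (n = 4) with siRELA and -0.04 ± 0.07 (n = 4) with siETS1, against -0.02 to 0.01 in controls. At 72 h they were 0.44 ± 0.05 (n = 2) with siJUN and 0.48 ± 0.06 (n = 4) with siRELA, against 0.38 ± 0.01 (n = 2) in controls. Of the risen genes 608 (94.1%) fell with siJUN, and of the fallen genes 667 (95.4%) rose, against 180 and 166 expected of independent lists. With siRELA 363 (56.2%) and 474 (67.8%) turned back (137 and 110 expected), and with siETS1 244 (37.8%) and 186 (26.6%) (96.4 and 124 expected). Other programme genes moved further the same way. With siETS1 50 risen genes rose and 99 fallen genes fell, with siRELA 29 and 12, and with siJUN 5 and 2. Across genes, which are not independent replicates, the change from 0 to 144 h and the knockdown change correlated at -0.88, -0.58 and -0.22 for siJUN, siRELA and siETS1 with split controls and at -0.88, -0.62 and -0.25 with shared controls. Simulated unchanged groups with shared controls gave -0.04. The covariances with split controls were -0.177, -0.09 and -0.0269, against -0.00157 in the simulation. The median programme gene turned back by a fraction of 0.53, 0.25 and 0.08 of its change.

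**Figure D3:**
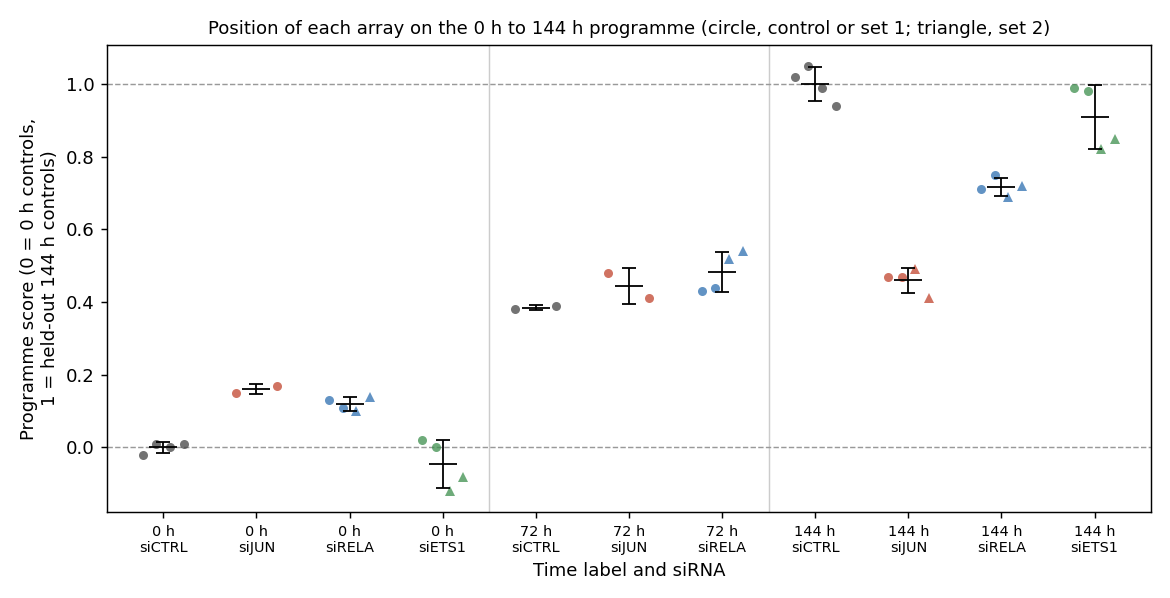
Programme score of each array (vertical axis, 0 for 0 h controls and 1 for held-out 144 h controls) by time label and siRNA (horizontal axis), with black bars for the mean and SD of each group. The 4 arrays with siJUN at 144 h lay between 0.41 and 0.49, below each held-out control, of which the lowest was 0.94.

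The overlap between knockdowns at 144 h was compared on shared and split controls. JUN and RELA knockdown raised 2287 genes in common (973 expected of independent lists) and lowered 2755 (1287 expected), and 525 moved in opposite directions. Shared genes included SERPINB4, PI3, IL24 and CXCL1 downward and LCE2A, CPA4, SEMA6A and SCN9A upward. Their changes correlated across genes at 0.68 with shared and 0.61 with split controls, against 0.33 in simulated unchanged groups with shared controls, and their covariance was 0.0638 and 0.06 against 0.0016. JUN and ETS1 knockdown raised 1425 genes in common (1102 expected) and lowered 1216 (953 expected), and 1746 moved in opposite directions. They correlated at 0.16 with shared and 0.10 with split controls, with covariances of 0.0117 and 0.00795. RELA and ETS1 knockdown raised 933 in common (805 expected) and lowered 787 (752 expected), and 1725 moved in opposite directions. No expected number was computed for opposite moves. For the pairs with ETS1 the counts in common alone therefore do not show net agreement. The changes of RELA and ETS1 knockdown correlated at 0.07 and 0.05, with covariances of 0.00403 and 0.00277. With shared controls the correlation of both pairs lay below the simulated 0.33 and the covariance above the simulated 0.0016, and split controls were not simulated.

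Knockdown at 0 h asked what the factors do in cells that, per the submitters' design, were transfected ahead of 4OHT. The exposure of these cells at collection is not stated. JUN promotes cell-cycle entry in dividing fibroblasts. With siJUN, ANKRD1 and CCN2, targets of mechanical and YAP signalling, and TGFB2 and INHBA, ligands of the TGF-beta family, rose, while the contractile gene CNN1 and the zinc transporter SLC39A6 fell. By at least 1 log2 unit 41 genes rose and 40 fell, and 2964 passed at any size, 42.4% of them higher and 75.5% after median subtraction. The count was 1336 without 0 h siJUN replicate 1, 1718 without replicate 2, 1286 with the siRNA set as a random block and 1763 with control replicates 1 and 2 alone. ANKRD1 (4.25 ± 0.21), PPME1 (2.40 ± 0.09), TNFSF4 (1.87 ± 0.16) and TGFB2 (1.77 ± 0.25) rose most, and CNN1 (-1.65 ± 0.23), SLC14A1 (-1.65 ± 0.22), SLC39A6 (-1.63 ± 0.09) and KRTAP1-5 (-1.55 ± 0.28) fell most. ANKRD1 (3.50) and TNFSF4 (3.92) in 0 h controls, and ANKRD1 (4.10) in 72 h controls, lay below the lower quartile of all probe sets (4.8). Detection was not tested, so the size of their rises is uncertain. The same holds for the change of any other gene with a group mean below 4.8. TGF-beta targets rose for 12 of 15 (13 adjusted over the list alone), with SKIL (1.43) and CCN2 (1.15), and this list passed with both correlations (adjusted p = 9.8e-15, adjusted p = 4.4e-05 with an estimated correlation). Glycolysis genes fell for 7 of 23, such as HK2 (-0.98) and ENO2 (-0.95) (9, and 1 higher, over the list alone, adjusted p = 0.00089, adjusted p = 0.29 with an estimated correlation), and mitosis genes rose for 8 of 29, such as PRC1 (0.65) (12 over the list alone, adjusted p = 2e-06, adjusted p = 0.3 with an estimated correlation). MMP3 (1.75) and INHBA (1.37) rose, and PTX3 (-1.20), EREG (-1.15) and FOXF1 (-0.95) fell.

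RELA knockdown at 0 h lowered interferon and NF-kB genes. IFI6 and CXCL10, the tight junction gene CLDN1 and the NF-kB inhibitor TNFAIP3 fell, and MMP3, the nuclear receptor NR4A2 and the BMP target ID1 rose. A full log2 unit or more separated 40 genes upward and 50 downward, and 5963 passed at any size, 49.1% of them higher and 38.1% after median subtraction. It fell to 3305 with the siRNA set as a random block and to 3803 with control replicates 1 and 2 alone. MMP3 (2.55 ± 0.17), SLITRK6 (1.98 ± 0.16), NR4A2 (1.95 ± 0.21) and TFPI2 (1.70 ± 0.13) rose most, and IFI6 (-2.30 ± 0.23), CXCL10 (-2.17 ± 0.25), CLDN1 (-2.00 ± 0.19) and TNFAIP3 (-1.75 ± 0.16) fell most. SLITRK6 (3.33) and NR4A2 (4.55) in 0 h controls, and CXCL10 (3.00) with siRELA, lay below the lower quartile of all probe sets (4.8). The sizes of these changes are uncertain. Interferon-stimulated genes fell for 21 of 26 (22 adjusted over the list alone, adjusted p = 6.2e-12, adjusted p = 0.26 with an estimated correlation). NF-kB genes fell for 13 of 21 and rose for 1, with PTX3 (-1.50) and ICAM1 (-1.45) (16 and 1 over the list alone, adjusted p = 1.5e-08, adjusted p = 0.23 with an estimated correlation). Antigen presentation genes fell for 12 of 14, such as TAP1 (-0.83) (adjusted p = 1.6e-06, adjusted p = 0.11 with an estimated correlation), and cholesterol genes for 13 of 18, such as HMGCS1 (-1.10) (14 over the list alone, adjusted p = 5.4e-07, adjusted p = 0.36 with an estimated correlation). Contractile genes fell for 7 of 14, such as TAGLN (-0.70) (11 over the list alone, adjusted p = 0.00049, adjusted p = 0.23 with an estimated correlation). CCL2 (-1.68) fell, and ID1 (1.60), EREG (1.37), NPC1 (1.25), CXCL5 (1.10) and CXCL8 (1.02) rose.

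ETS1 knockdown at 0 h gave the fewest large changes, with 6 genes higher and 3 lower by at least 1 log2 unit and 3444 past the threshold at any size (1774 higher and 1670 lower, and 1424 and 1458 after median subtraction). Only 1221 passed with the siRNA set as a random block and 1567 with control replicates 1 and 2 alone. SERPINB7 (1.20 ± 0.23), SEMA7A (1.18 ± 0.16), CPA4 (1.15 ± 0.15) and the imprinted MEST (1.02 ± 0.13) rose, and the hyaluronan gene CEMIP (-1.20 ± 0.23), the folding enzyme PDIA3 (-1.05 ± 0.25), ETS1 itself (-1.03 ± 0.07) and TNFRSF11B (-0.98 ± 0.15) fell. Antigen presentation genes fell for 11 of 14, such as ERAP2 (-0.50) (12 over the list alone, adjusted p = 2.3e-07, adjusted p = 0.079 with an estimated correlation), and NF-kB genes fell for 6 of 21, such as TNIP1 (-0.50) (adjusted p = 0.0038, adjusted p = 0.51 with an estimated correlation). MMP3 (0.93) and SLC2A3 (0.80) rose, and FOS (-0.90), CALR (-0.80), IL6 (-0.70), MYL9 (-0.62) and LMNB1 (-0.60) fell. IL6 and TNIP1 did not pass with siRNA set 1 alone (-0.30, adjusted p = 0.18, and -0.23, adjusted p = 0.096) or with only the compared groups in the fit (adjusted p = 0.069 and 0.06).

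At 72 h JUN knockdown raised genes of matrix and sterol synthesis. ANKRD1, TGFB2 and the collagen cross-linker LOX rose, and IL1B, IL1A and EREG, which had risen from 0 to 72 h in controls, fell. By at least 1 log2 unit 56 genes rose and 23 fell, and 2560 passed at any size, 38.0% of them higher and 79.0% after median subtraction. The count rested on 2 arrays on each side and was 1085 and 1464 without 72 h control replicate 1 and 2 and 1362 without 72 h siJUN replicate 1, and 1227 with the siRNA set as a random block. ANKRD1 (3.65 ± 0.24), TGFB2 (2.25 ± 0.28), TNFSF4 (2.05 ± 0.19) and MAMDC2 (2.0 ± 0.13) rose most, and IL1B (-2.30 ± 0.27), EREG (-1.60 ± 0.16), WNT16 (-1.55 ± 0.37) and ESM1 (-1.50 ± 0.22) fell most. WNT16 did not pass without 72 h control replicate 1 (-1.40, adjusted p = 0.059) or 72 h siJUN replicate 1 (-1.15, adjusted p = 0.11). Cholesterol genes rose for 14 of 18 (17 adjusted over the list alone), such as DHCR7 (1.50) and HMGCS1 (1.05) (adjusted p = 3e-15, adjusted p = 0.15 with an estimated correlation). Matrix genes rose for 13 of 26 and fell for 1, such as LOX (1.20) and COL1A1 (0.90) (14 and 2 over the list alone, adjusted p = 8.5e-11, adjusted p = 0.15 with an estimated correlation), and glycolysis genes fell for 13 of 23 and rose for 1, such as HK2 (-0.85) (15 and 1 over the list alone, adjusted p = 5.3e-06, adjusted p = 0.17 with an estimated correlation). CCN2 (1.45), CCN1 (1.30) and LUM (1.15) rose, and SPRY4 (-0.80) and DUSP6 (-0.65) fell. With only the compared groups in the fit WNT16, CCN1, HMGCS1 and HK2 did not pass (adjusted p = 0.18, 0.071, 0.061 and 0.057).

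RELA knockdown at 72 h lowered cell-cycle genes together with NF-kB genes. The matrix proteases MMP10 and MMP12 rose, and ICAM1, which holds leukocytes, and IFI27 fell. By at least 1 log2 unit 48 genes rose and 47 fell, and 4523 passed at any size (2001 higher and 2522 lower, and 2131 and 1903 after median subtraction). The count was 2239 and 2640 without 72 h control replicate 1 and 2 and 2836 with the siRNA set as a random block. MMP10 (2.60 ± 0.30), MMP12 (2.40 ± 0.27), PIEZO2 (1.78 ± 0.24) and NR4A2 (1.65 ± 0.26) rose most, and IFI27 (-2.03 ± 0.32), ICAM1 (-2.02 ± 0.19), H1-4 (-1.95 ± 0.14) and IFI6 (-1.92 ± 0.28) fell most. Mitosis genes fell for 24 of 29, such as CCNA2 (-0.95) and CDC20 (-0.87) (26 over the list alone, adjusted p = 1.1e-16, adjusted p = 0.074 with an estimated correlation), and replication genes for 19 of 26, such as PRIM1 (-0.77) (20 over the list alone, adjusted p = 1.9e-06, adjusted p = 0.31 with an estimated correlation). NF-kB genes fell for 13 of 21 and rose for 2, with TNFAIP3 (-1.62) and NFKBIA (-1.02) (14 and 2 over the list alone, adjusted p = 1.3e-05, adjusted p = 0.34 with an estimated correlation). Contractile genes fell for 7 of 14, such as TPM1 (-0.75) (8 over the list alone, adjusted p = 0.0027, adjusted p = 0.29 with an estimated correlation). BMP2 (1.18) and NPC1 (1.07) rose, and IL1B (-1.02) and THY1 (-0.87) fell. With only the compared groups in the fit NR4A2 and IL1B did not pass (adjusted p = 0.066 and 0.055).

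Interaction contrasts asked whether a knockdown acted differently at 144 h than at the other time labels. For JUN, 371 genes had a higher and 268 a lower effect at 144 h than at 0 h by at least 1 log2 unit, of 7744 past the threshold. SEMA6A (4.18 ± 0.31), LCE2A (3.96 ± 0.39), LRRN3 (3.65 ± 0.33) and CPA4 (3.65 ± 0.22) moved up most, and SERPINB4 (-5.21 ± 0.44), PI3 (-3.82 ± 0.27), PTGS2 (-3.80 ± 0.37) and HEPHL1 (-3.56 ± 0.32) down most. Its effect on CNN1 turned from a fall at 0 h to a rise at 144 h (difference 3.23), and its effect on SKIL from a rise to a fall (-1.69). Against 72 h, 246 genes moved up and 231 down, of 6058, led by LCE2A (3.59 ± 0.43), IL1B (3.47 ± 0.32) and SERPINB4 (-6.04 ± 0.49), and the effect on cholesterol genes dropped for 16 of 18 and rose for 1, such as INSIG1 (-1.99) (17 and 1 over the list alone, adjusted p = 8.5e-11, adjusted p = 0.23 with an estimated correlation). For RELA, 232 genes moved up and 88 down between 0 and 144 h, of 6130, led by KRTAP1-5 (4.41 ± 0.30), CPA4 (3.55 ± 0.20), SERPINB4 (-3.34 ± 0.39) and NR4A2 (-3.29 ± 0.28). The higher share moved from 46.2% to 75.5% after median subtraction, which shifted the median of all genes by 0.11, and the count was 3600 with the siRNA set as a random block and 3894 with control replicates 1 and 2 alone. Against 72 h 182 moved up and 89 down, of 4778, led by SCN9A (3.44 ± 0.30) and SERPINB4 (-3.59 ± 0.44), and the higher share moved from 49.6% to 67.2%. With the set as a random block the counts against 72 h were 3987 for JUN and 2792 for RELA. The effect of RELA knockdown on contractile genes rose for 11 of 14 in both contrasts, such as TAGLN (1.98 and 2.27), and passed with both correlations (adjusted p = 4.1e-11 and 3e-12, adjusted p = 0.029 and 0.023 with an estimated correlation). For ETS1, 9 genes moved up and 21 down between 0 and 144 h, of 2119, led by ADAMTS5 (-1.62 ± 0.21), OLR1 (-1.52 ± 0.24), MMP10 (-1.50 ± 0.32) and CSRP2 (1.23 ± 0.22). The ETS1 count was 203 with the siRNA set as a random block, where MMP10 did not pass (adjusted p = 0.053), and 560 with control replicates 1 and 2 alone.

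Sets 1 and 2 of each siRNA were compared where both existed. For siJUN at 144 h 0 genes differed in the limma fit (731 at an unadjusted p under 0.05), and the effects of the sets correlated across genes at 0.97 with shared and 0.94 with split controls. For siRELA 3 genes differed at 0 h, ADAMTS1, E2F7 and ENO2 (chosen after their values were seen), 399 at 72 h and 254 at 144 h, among the latter SPP1 (set 1 minus set 2, 1.60 ± 0.25) and BMP2 (-0.90 ± 0.17). For siETS1 2667 differed at 0 h and 1880 at 144 h, with 29 and 30 by at least 1 log2 unit. HAS2 (-2.25 ± 0.24) and CCL2 (1.60 ± 0.29) differed at 0 h, and SERPINB4 (1.70 ± 0.29), CCL20 (1.40 ± 0.11) and KRTAP1-5 (-1.35 ± 0.14) at 144 h. The effects of the siETS1 sets correlated at 0.41 at 0 h and 0.66 at 144 h with split controls. Each set had 2 arrays per group, and single arrays moved these counts by more than 1.5 times. At 0 h the siETS1 count was 1742 and 1286 without replicates 1 and 2 of set 1 and 1321 and 1769 without those of set 2. At 144 h it was 651 without replicate 2 of set 1 and 1174 and 804 without replicates 1 and 2 of set 2. The siRELA count at 72 h was 103 and 79 without replicates 1 and 2 of set 1 and 120 and 58 without those of set 2. At 144 h it was 67 and 77, and 116 and 57, in the same order, and at 0 h it was 1 without replicate 1 of set 1 and 0 without each of the other 3 arrays.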

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

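The regrouping tests and the tests of rescaled replication genes, of 144 h control replicates 7 and 8 and of a recurring set difference were written before the result was seen, and those of shared controls, of one siRNA set, of changed array scale, of the 0 to 144 h axis and of other cell types after it. Values far from the rest of their group were sought with the Dixon test in 280 groups of values, where chance alone flags about 1 in 20 groups, or 14, and 15 were found.

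Chance assignment of arrays to groups was tested by refitting with the arrays regrouped, the real grouping included. Comparisons with a group of 2 arrays were not regrouped. Those with siJUN at 0 or 72 h or with 72 h controls were therefore not tested. In each comparison that was tested 1 split, the real one, reached the real count. Between 0 and 144 h controls this was 1 of 100 splits, with 13348 genes against at most 9706. At 0 h it was 1 of 35 for siRELA (5963 against at most 1) and for siETS1 (3444 against at most 4). At 144 h it was 1 of 100 for siJUN (10188 against at most 6677), siRELA (7754 against at most 4110) and siETS1 (7125 against at most 2839). Between knockdowns it was 1 of 35 for JUN and RELA (7156 against at most 928), JUN and ETS1 (10236 against at most 4255) and RELA and ETS1 (9410 against at most 2894). For the difference of the effect at 144 h from that at 0 h it was 1 of 100 for RELA (6130 against at most 4093) and for ETS1 (2119 against at most 872). Chance can be excluded at that level only, and the large counts of some other splits point to structure among the samples, since regrouped arrays still mix real groups in unequal parts.

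The difference between siETS1 sets 1 and 2 had 2 explanations, and both were left open. A difference carried by the set itself would recur at both time labels, and the set differences at 0 and 144 h correlated at 0.41 over all genes and at 0.87 over the 736 genes past the threshold between sets at both labels. A difference in how far the cells stood along the 0 to 144 h change would follow that change, and the set differences at 0 and 144 h correlated with the control change at 0.77 and 0.80 over those 736 selected genes but at only 0.33 and 0.44 over all genes. Both values are consistent with their explanation, so the arrays may differ by siRNA sequence, by culture or by both. The explanations do not exclude each other, so knowing what the set number marks would not by itself decide between them. The level of ETS1 also differed between sets at 0 h, at 6.8 and 6.9 in set 1 and 7.2 on both arrays of set 2. At 144 h it was 6.1 and 6.2 in set 1 and 6.1 and 6.0 in set 2.

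The knockdown effects differed between time labels. For JUN 7744 genes and 6 lists passed between 0 and 144 h, and 6058 genes and 11 lists between 72 and 144 h, with 0 lists in either under an estimated correlation. For RELA 6130 genes and 8 lists passed between 0 and 144 h and 4778 genes and 8 lists between 72 and 144 h, with 1 list in each under an estimated correlation. For ETS1 2119 genes and 8 lists passed, with 0 lists under an estimated correlation, but only 203 genes with the siRNA set as a random block and 560 with control replicates 1 and 2 alone, so the size of this difference depends on the model. The effect of siRELA on RELA itself was weaker at 144 h than at 0 h by 0.81 (adjusted p = 1.1e-09) and than at 72 h by 0.66 (adjusted p = 1.4e-06). The effect of siETS1 on ETS1 was larger at 144 h than at 0 h (-0.49, adjusted p = 0.00037), and that of siJUN on JUN was weaker at 144 h than at 72 h by 0.39 (adjusted p = 0.00083).

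Single arrays stood apart for several values. JUN was 8.0 in 0 h siRELA set 1 replicate 2, 7.60 in 72 h siRELA set 1 replicate 2 and 7.30 in 144 h siJUN set 2 replicate 2. RELA was 8.20 in 0 h control replicate 3, 7.0 in 72 h siRELA set 2 replicate 1 and 8.50 in 144 h siJUN set 1 replicate 1. Most of these lay one rounding step of 0.1 from the rest of their group. The mean level of matrix proteases was 8.81 in 0 h siRELA set 2 replicate 1 and 8.47 in 144 h siJUN set 1 replicate 2. Replication genes stood at 5.82 in 72 h siRELA set 2 replicate 2, chromatin genes at 6.51 in 144 h control replicate 7 and CDK inhibitors at 6.77 in 0 h control replicate 4. ETS family genes stood at 6.68 in 0 h control replicate 2, outputs of RAS and ERK at 7.52 in 0 h siRELA set 2 replicate 2 and housekeeping genes at 8.57 in 144 h siJUN set 1 replicate 1. Interferon-stimulated genes stood at 7.01 in 144 h control replicate 6, where the next array had 6.72.

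Probe sets outside the gene tests also changed by at least 1 log2 unit. Among the 1244 with several symbols these were 81 between 0 and 144 h controls and 19, 19 and 8 with siJUN, siRELA and siETS1 at 144 h. Among the 20831 with no symbol listed they were 1523, 339, 134 and 98.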

How the results depend on the processing

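The main alternatives were set before the data were examined, and those with rounding noise, without 144 h control replicates 7 and 8, with one siRNA set, with rescaled programme scores and all those for the set differences were added after the data were seen. No target, named gene or programme score changed direction in any setting. A second quantile normalization moved 1 of 42 main results, the siRELA set difference at 0 h (12 genes, main 3). Subtraction of each array's median moved 1 of 42, the siRELA set difference at 144 h (149, main 254), and it changed the balance of higher and lower calls, since by construction medians of rounded values move in steps of 0.1. Leaving out the dimmest genes, averaging probe sets, eBayes with trend, array weights, 17 means and rounding noise moved none of 27 results each. With the siRNA set as a random block (correlation 0.24) 12 of 27 results moved downward. The counts were then 2924 for 72 against 0 h controls, 1286, 3305 and 1221 for siJUN, siRELA and siETS1 at 0 h, 1227 and 2836 for siJUN and siRELA at 72 h, and 4715 and 3593 for siRELA and siETS1 at 144 h. For the differences of an effect they were 3600 and 203 for RELA and ETS1 between 0 and 144 h and 3987 and 2792 for JUN and RELA between 72 and 144 h. With the replicate number as a block the siETS1 count at 144 h was 4568 (main 7125) and the other 26 results held. Only 5 of 28 knockdown arrays correlated best with the control of the same number. No rate expected of unpaired arrays was computed, so whether the numbers pair the arrays was left open. Correlations with a control of another number reached 0.5 (144 h siETS1 set 2 replicate 2). With control replicates 1 and 2 alone the counts were 1763, 3803 and 1567 for siJUN, siRELA and siETS1 at 0 h, 4727 and 3559 for siRELA and siETS1 at 144 h, and 3894 and 560 for the RELA and ETS1 differences between 0 and 144 h. With only the groups of a comparison in the fit JUN at 72 h was unchanged at -0.70 but lost its call (adjusted p = 0.061), as did 8 of 347 named genes. Without a minimum fold change the share turned back was 57.6% of fallen genes with siJUN, 29.1% of fallen genes with siRELA and 20.4% of risen genes with siETS1, all lower than in the main setting. The programme scores of siJUN, siRELA and siETS1 stayed at 0.45 to 0.48, 0.70 to 0.74 and 0.88 to 0.94 with other controls defining the programme, without a minimum fold change, without replication and mitosis genes, after a second quantile normalization and with single knockdown arrays left out, while subtraction of medians cancels in this score by construction, and by siRNA set they were 0.47 and 0.45, 0.73 and 0.71, and 0.98 and 0.83. Of 164 list results 161 lost their call with an estimated correlation, which left 3, and 33 without dim genes. Among named genes 3 of 215 lost their call with set 1 alone, 2 of 347 with the random block and 2 of 3598 tests with single arrays left out. Leaving out single arrays moved 28 of 340 main results and ended 1 call, JUN with siJUN at 0 h (-0.35 to -0.25). The counts ranged from 1336 to 2617 for siJUN at 0 h, 2912 to 4624 for 72 against 0 h controls, 1085 to 1736 for siJUN and 2239 to 4378 for siRELA at 72 h. The set differences ranged from 1286 to 1769 for siETS1 at 0 h, 651 to 1412 for siETS1 at 144 h, 0 to 1, 58 to 120 and 57 to 116 for siRELA at 0, 72 and 144 h. Apart from the step of the medians the cause was not tested.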

Other observations

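The genes in the next sentences were chosen after their values were seen. IL1B, which starts the cytokine cascade of senescent cells, stood at 9.85 in 0 h controls, 10.55 at 72 h and 7.03 at 144 h. Against controls of the same label, IL1B was lower with siJUN at 72 h (-2.30 ± 0.27, adjusted p = 2.85e-07) and higher at 144 h (1.18 ± 0.17, adjusted p = 2.75e-07). The difference of the effect between 72 and 144 h was 3.47 ± 0.32 (adjusted p = 3.1e-10). The level of IL1B with siJUN was 8.25 at 72 h and 8.20 at 144 h, so the change of sign came with the fall in controls. With siRELA IL1B was likewise lower at 72 h (-1.02) and higher at 144 h (1.35), at levels of 9.53 and 8.38. Its receptor gene IL1R1 rose in controls by 144 h (2.40) and fell with siJUN (-2.12).

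PPME1, a methylesterase of the phosphatase PP2A, rose from 6.70 in 0 h controls to 9.07 in 144 h controls. JUN knockdown at 0 h brought it to 9.10. The zinc transporter SLC39A6 fell from 9.82 to 7.65 between the same labels and stood at 8.20 with siJUN at 0 h. ANKRD1, a target of mechanical signalling, stood at 3.50 in 0 h controls and 7.75 with siJUN at 0 and at 72 h. These siJUN arrays came from one set with 2 arrays per time label.

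The tests of shared controls, of one siRNA set, of changed array scale and of other cell types below were chosen after the result was seen. JUN knockdown at 144 h moved the programme back toward its 0 h level, and 3 technical explanations were tested. With split controls, so that no array served both sides, the score was 0.46 (SD 0.04) against a lowest held-out control of 0.94, which excludes shared controls. The higher of the set means was 0.47, which excludes an effect of one set alone, and a change of scale of whole arrays, which would move genes by their level alone, is excluded since at least 81.2% of the risen genes fell and of the fallen genes rose in each of 10 bins of control level. At the earlier labels the score with siJUN lay above controls instead (0.16 against 0.00 at 0 h, 0.44 against 0.38 at 72 h). JUN holding part of the programme in place therefore remains a hypothesis for 144 h alone. The level of JUN was only 19.5% lower with siJUN than in controls at 144 h (-0.31). In controls JUN fell further between 0 and 144 h (34.6%, -0.61), while the programme rose. JUN protein was not measured, and an effect of siJUN on these genes apart from senescence was not tested. A larger loss of JUN at 144 h would test the hypothesis.

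Replication genes stood higher at 144 h than at 0 h in controls, and mitosis genes less so, but neither list passed with an estimated correlation (adjusted p = 0.4 and 0.61), and only the replication list was tested further. After rescaling the median change of the replication list was at least 0.67 (SE 0.11). Array medians over genes already lay at 6.1 to 6.2, so rescaling could hardly move this value and cannot exclude a shift by scaling. Control replicates 7 and 8 are excluded as the source, since without them the median change was 0.71 (0.68 with all). The highest median of 4 lists of markers of other cell types was 0.18 (SE 0.31), so cells of another type cannot be told apart from a change within the fibroblasts. Density or culture state of the 0 h cells may also differ, and an uninduced group kept for 144 h would test it. The labels are not known to be collection times either, so the exposure behind this difference is open.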
